A study of Saccharolobus solfataricus P2 with 8 samples.

How the data were processed

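RNA from Saccharolobus solfataricus P2 grown to mid-log phase on glucose, cellobiose or cellulose was sequenced, per the labels, in 3 RACE libraries and 5 cDNA libraries. For RACE, RNA was treated with tobacco acid pyrophosphatase, an RNA adapter was ligated to its 5′ ends, random hexamers primed the cDNA, and cDNA of 150 to 500 bp was taken from a gel. For the cDNA libraries, DNase-treated RNA was reverse transcribed from random hexamers, which keeps no strand. The 3 RACE libraries shared 1 flow cell, the glucose and cellobiose cDNA libraries shared another, and the cellulose cDNA library came from a different flow cell.

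Each library has a list of placements and a coverage file. The authors deposited placements as read name, first base, last base and strand, with a line for each placement of a read that was placed more than once. Placements were 31 to 38 nt long, 85.5% to 89.4% of them 36 nt, and a read had up to 34. The deposited coverage values are raw counts of placed reads over each position, both strands together and without normalization, as the values show. Coverage was never below the depth rebuilt from the placements and held 2.29% to 3.36% more in total. Whether this comes from placements that the lists lack or from longer extents of the listed ones was not determined. The aligner and its filters are not given in the sources used here. Read counts were taken from the placements, and coverage was used for the step at start sites, the blocks of the locus and the map of regions.

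No gene annotation of the chromosome was used here, so genes were replaced by 5985 windows of 500 nt, a fallback fixed before the data were examined. The first rules for start sites and named items were fixed then too, and parts of them were changed later, as stated below. A placement was counted in the window that holds its middle base. Leaving out the abundant locus and setting repeat windows apart were decided after the data were examined. The locus from 871501 to 876500, 10 windows that each held over 1% of the placements of every cDNA library, was left out of window counts and library sizes. A window was called a repeat window when over 50% of its placements came from reads with more than 1 placement, which took in 751 windows. The other windows are called single-copy. Windows with at least 100 placements over the 5 cDNA libraries, a mean of 20, were measured, 2601 in all.

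The design planned an edgeR quasi-likelihood F test with the 2 glucose and 2 cellobiose libraries as replicates. The libraries of each pair differed by no more than sampling noise over windows with at least 20 singly placed reads, while a simulation with a 20% spread between replicates gave a chi-square per degree of freedom of 2.18. Whether the labels mean repeats of the culture or of the sequencing is not given. They were counted here as runs of 1 sample, and a test on them compares the libraries and not the growth conditions. In its place, placements were summed per carbon source, scaled by TMM factors from edgeR (0.986 for glucose, 0.888 for cellobiose and 1.14 for cellulose), and compared as ratios. RPM for cDNA are placements in each 1000000 of the scaled total outside the locus. Exact conditional Clopper-Pearson intervals at 95% cover counting error only. A window was called higher or lower when its ratio was at least 2-fold and its interval excluded equality, a rule set after the comparison of the runs. The edgeR fit was still made on windows, with filterByExpr, all 5 libraries and adjusted p under 0.05 by Benjamini-Hochberg, and its counts are given with the alternatives. The runs share only a number across carbon sources, so numbers were not taken as pairs. Their deviations in the 2 pairs had r = -0.022 across 2601 windows. This cannot decide the pairing, since deviations at the level of sampling noise would be near uncorrelated either way.

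Start sites were positions with at least 5 singly placed 5′ ends in at least 2 RACE libraries and the highest count within 25 nt on the strand. Reads with more than 1 placement were left out of the sites, and 77 sites in the locus were left out of the counts, both set after the files were examined. For RACE ratios, 5′ ends within a window of 5 nt around the site were expressed as RPM, in each 1000000 singly placed ends of the library, 10 RPM was added, and sites with at least 50 ends in 1 of the 2 libraries were compared, without a test. The cDNA step was the log2 ratio of mean coverage over 100 nt downstream and upstream, with a depth of 0.5 added to each, and over 1 was called a step. It was compared with the step at 19956 random positions. RACE ratios of single-copy windows at least 2-fold apart in cDNA, from singly placed reads and with at least 50 in 1 of the 2 libraries, were placed among those of 10000 random lists of windows of the same size matched in 10 bins of RACE reads.

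Named windows were the 12 single-copy windows with the largest ratio each way per comparison among those called whose runs did not overlap between the carbon sources, with stretches of at least 3 adjoining called windows added. Named sites were the 10 with the most reads and the 8 highest and 8 lowest ratios per RACE comparison. Abundant windows, and the strongest site in a named window, were chosen after their values were seen.

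The steps were tested on simulated data. Of 200 windows with planted changes, edgeR recovered 83% of those changed 2-fold and 100% of those changed 4-fold, with 10 false calls. The ratio rule found 89% of those changed 4-fold, with 4 unchanged windows called and a median error of 0.113 in log2. Its recovery of 2-fold changes was not counted. Each simulated window was drawn on its own with counting noise only. The simulation held no spread between libraries, no trend with abundance and no reads shared between windows. False calls in the real comparisons may therefore be more frequent. Of 600 planted start sites, 99.5% were found at 10 reads and 100% at 30 and 100 reads, with 0 others. The simulated background was only 0.214 ends per nt, far below the read minimum for a site, so other sites could hardly arise. The count of others therefore does not measure how many sites called in the real RACE libraries are false.

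Alternatives covered scaling, the low-count filter, multiply placed reads, reads sharing a position, the site rules, the pseudocount and leaving out each run. Gene lists, the leaderless share, site locations relative to genes, promoter composition, Shine-Dalgarno motifs and operon continuity need gene positions or the sequence and were not analysed here. The tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.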

Results

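RNA was measured in the archaeon Saccharolobus (Sulfolobus) solfataricus P2, a thermoacidophile grown here at 80 °C and pH 3.5 in mineral medium with glucose, cellobiose (a glucose disaccharide) or microcrystalline cellulose as its sole carbon source at 0.4% w/v. The series title names a transcriptome map at single-base resolution as the aim. There were 8 samples. The 5′ ends of transcripts were sequenced with strand in 3 RACE libraries, 1 per carbon source. Random fragments of total RNA were sequenced without strand in 5 cDNA libraries, 2 from glucose, 2 from cellobiose and 1 from cellulose. The RACE libraries held 527933 reads from glucose, 1752729 from cellobiose and 1537630 from cellulose. The cDNA libraries held 904359 and 1917552 reads from glucose, 1207119 and 1684820 from cellobiose and 1414089 from cellulose. Positions below are 1-based on the chromosome of 2992245 nt to which the reads had been placed. No gene names were assigned here, so regions and start sites are named by position and strand.

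Most cDNA reads lay in 1 locus of 5000 nt, from 871501 to 876500. It took 76.8% of glucose reads (95% Clopper-Pearson interval 76.8 to 76.9), 87.1% of cellobiose reads (87.1 to 87.2) and 88.8% of cellulose reads (88.7 to 88.8). In the RACE libraries the locus took 7.26% of reads from glucose (7.19 to 7.33), 12.7% from cellobiose (12.6 to 12.7) and 16.7% from cellulose (16.7 to 16.8). Both assays gave their lowest locus share with glucose and their highest with cellulose. The 2 glucose cDNA libraries, at 77.8% (77.7 to 77.8) and 76.4% (76.3 to 76.4), differed by more than their intervals, so counting error understates the error of these shares. Clopper-Pearson and counting intervals throughout cover counting error only and take reads as independent, which was not tested. The comparison of runs over windows below leaves out the locus, so it does not take in this difference. Within the locus, cDNA coverage fell into a block from 871684 to 873134 and a longer block from 873354 to 876394, of 1451 and 3041 nt. RACE 5′ ends in and just upstream of both blocks were almost all on the plus strand, with 174853 plus-strand and 96 minus-strand placements at the longer block with cellulose. Outside the locus, 155237 to 453094 cDNA reads per library remained.

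**Figure D1:**
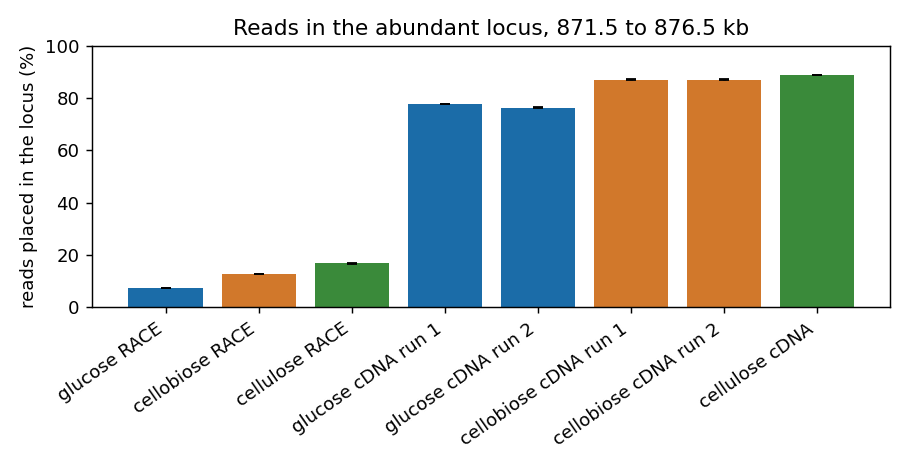
Bars give the percentage of reads of each of the 8 libraries placed in the locus from 871501 to 876500, with 95% Clopper-Pearson intervals as error bars, blue for glucose, orange for cellobiose and green for cellulose. The share runs from 7.26% to 16.7% in RACE and from 76.4% to 88.8% in cDNA.

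Over 500 nt windows outside the locus, the 2 glucose cDNA libraries differed by no more than sampling noise would give (chi-square per degree of freedom 0.994 over 3738 windows, p = 0.608), and the 2 cellobiose cDNA libraries gave 1.025 over 2727 windows (p = 0.174). For the 8 pairs of libraries from different carbon sources the same value was 4.87 to 9.66. The series text calls 2 of the cDNA samples replicates, the sample titles number both pairs, and neither gives the kind of repeat. Each pair was counted here as 1 sample and its reads were summed, which leaves 1 cDNA sample per carbon source. Differences between carbon sources below are differences between these libraries and have no replicate check.

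Levels are given in RPM, which for cDNA are placements in each 1000000 outside the locus after TMM scaling, and for RACE singly placed 5′ ends in each 1000000 of the library. Outside the locus, the single-copy window with the most cDNA in the mean over carbon sources was 1575001 to 1575500, at 23721 RPM with glucose, 38704 with cellobiose and 13491 with cellulose. It held a plus-strand RACE site at 1575295. A stretch of 11 windows from 333501 to 339000 held 95452 RPM with glucose, 78957 with cellobiose and 27694 with cellulose, and its strongest site lay at 333726 on the plus strand. Other abundant windows started at 2641001, 2157501, 49501, 224501 and 954001.

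The RACE libraries gave 4840 transcription start sites outside the locus, 2347 on the plus strand and 2493 on the minus strand, with a further 77 inside it. A site was a position with at least 5 singly placed read 5′ ends in at least 2 of the 3 libraries and the highest count within 25 nt. Of these sites, 1119 had at least 100 reads over the 3 libraries and 178 had at least 1000. By reads summed over the 3 libraries, which differ in depth, the strongest was 816020 on the plus strand, with 81997 RPM from glucose, 27693 from cellobiose and 23066 from cellulose. Next came 2157599 on the plus strand (27875, 32249 and 17862 RPM, in the same order) and 184482 on the minus strand (18747, 11235 and 21586 RPM). In mean RPM 184482 stood below 763527 on the plus strand (32643, 13168 and 13368 RPM), which had fewer reads. The other 7 of the 10 sites with most reads were 1350711, 763527, 829584 and 755726 on the plus strand and 377801, 2189899 and 42739 on the minus strand. Reads were concentrated at the site itself: it held a median of 73.4% of the 5′ ends within 25 nt at sites with at least 1000 reads, and 43.2% over all sites. Primary 5′ ends were not separated here from ends made by RNA processing.

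cDNA coverage stepped up at the stronger start sites. Coverage over the 100 nt downstream was more than 2-fold that of the 100 nt upstream at 82.0% of the 178 sites with at least 1000 reads (Clopper-Pearson interval 75.6 to 87.4), with a median log2 step of 3.56. The share was 56.5% (53.3 to 59.7) at the 941 sites with at least 100 but under 1000 reads, 29.2% (27.1 to 31.5) at the 1717 sites with at least 30 but under 100 and 21.5% (19.7 to 23.3) at the 2004 sites with under 30. At random positions, which were not matched on coverage, it was 14.3% (13.8 to 14.8). A fall of more than 2-fold was seen at 14.1% of random positions, 6.44% of sites with under 30 reads and 1.69% of sites with at least 1000. Site 2157599 had a mean depth of 2860 downstream against 0.02 upstream, and 42739 had 399 against 0.01. The strongest site, 816020, had 106 against 38.6, and 755726 showed no rise, at 22.9 against 40.9. Over all 4840 sites 33.3% had the step.

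**Figure D2:**
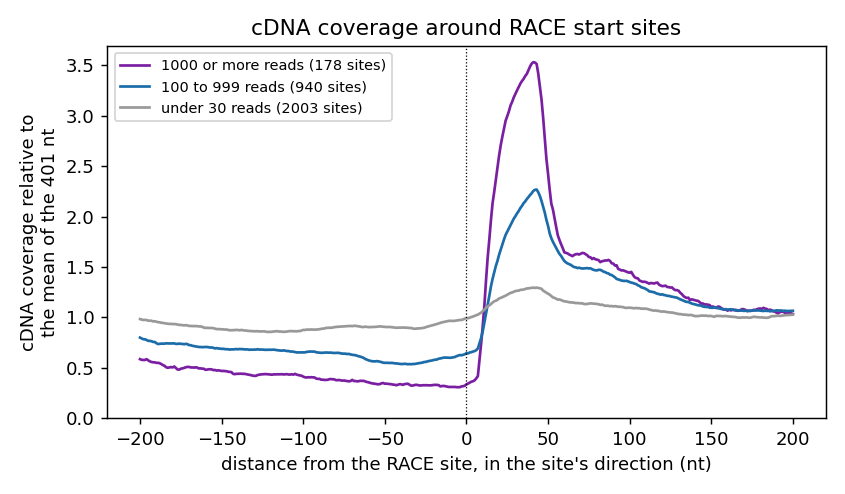
Lines give the mean cDNA coverage, relative to each site's mean over the plotted stretch, against the distance in nt from the RACE site in the direction of transcription, for sites with at least 1000 reads, at least 100 but under 1000 reads and under 30 reads. Coverage rises just past the site in the strongest class, where 82.0% of sites had a step of over 2-fold, and changes least in the weakest, where 21.5% had one.

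The cellobiose and glucose comparison asks which regions differ between growth on the disaccharide and on its monomer. With cellobiose, cDNA was higher over 854501 to 856500 (1947 RPM against 547 with glucose, log2 ratio 1.83, counting interval 1.67 to 2.00), in 2 adjoining windows from 77501 to 78500 (4.76-fold and 4.03-fold), in 72501 to 73000 (3.37-fold) and in 597501 to 598000 (4.28-fold). The highest ratio was that of 1350001 to 1350500, at 502 against 98.5 RPM (log2 2.35, interval 1.98 to 2.73). cDNA was lower with cellobiose over 547501 to 550000 (215 RPM against 559, log2 -1.38, interval -1.71 to -1.07) and in 2935501 to 2936000 (81.6 against 270, log2 -1.73). Of 2601 windows measured, 122 were at least 2-fold higher with an interval above 0 and 47 at least 2-fold lower, and 2432 did neither.

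Windows in repeated sequence, where most placements come from reads placed at several positions, made up much of the higher group. They gave 77 higher and 1 lower of 609, against 45 higher and 46 lower of the 1992 single-copy windows. A read with several placements counted in the window of each, so repeat windows share reads and are not independent of each other. The same rule applied between the 2 runs of 1 carbon source called 15 windows for glucose and 32 for cellobiose. Among the other named single-copy windows, those at 835501 and 836001 were higher by 3.78-fold and 3.86-fold, 1717001 by 3.47-fold and 32501 by 3.29-fold. Those starting at 1751001, 2936501, 361001, 1168001, 2704501, 546501, 392001 and 395501 were 2.34-fold to 2.94-fold lower. With library totals in place of TMM scaling, the median of all windows moved by -0.15 and the split turned, to 74 higher and 89 lower. Without the low-count filter there were 246 higher and 161 lower. The lower count also rested on single runs: it was 105 without cellobiose run 2, 80 without cellobiose run 1 and 26 without glucose run 2.

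The RACE start site with the highest cellobiose to glucose ratio was 597874 on the minus strand, inside the window that was 4.28-fold higher in cDNA, with 506 RPM against 30.1 (log2 ratio 3.68, with 10 RPM added to each). Sites 855560 (181 against 20.9 RPM), 835771 (181 against 16.2) and 835742 (71.3 against 4.63), all on the plus strand, lay in the cDNA windows 855501 and 835501, which were higher too. Further high sites were 2248934 on the minus strand and 1158916, 761772 and 2250084 on the plus strand. The glucose side of these ratios rests on few ends: 3, 1, 6 and 36 at these sites in order, 13 at 597874, and 9, 7 and 2 at 855560, 835771 and 835742. The lowest ratios were at 426221 (108 against 510), 666126 (184 against 788) and 728964 (67.9 against 255), all on the plus strand, and the strongest site of all, 816020, was also among the 8 lowest, with 1779097, 2935330, 2018873 and 29572. Of 1423 sites with at least 50 reads in 1 of the 2 libraries, 117 were at least 2-fold higher and 37 at least 2-fold lower. The glucose library had 431639 singly placed ends and the cellobiose library 1487260. A site thus passed this minimum at a lower RPM through cellobiose, which favours higher sites in the split. With 50 RPM added in place of 10, 28 were higher and 19 lower. Of the 12 named windows higher in cDNA, 10 had a site in them or within 100 nt, and of these 9 strongest sites 8 were higher with cellobiose. The exception was the highest cDNA window, 1350001, whose site 1350156 on the plus strand had 92.1 RPM with cellobiose and 118 with glucose. Of the 12 lower in cDNA, 8 had a site, of which 5 were lower and 3 higher. Over the 35 single-copy windows at least 2-fold higher in cDNA that had enough RACE reads, the median RACE log2 ratio was 0.70, above each of 10000 random lists matched on RACE reads (highest 0.53). Over the 25 at least 2-fold lower it was -0.28, below each random list (lowest -0.23). Called windows adjoin in places and are not independent, while the random lists drew windows singly, so the range of the lists may be too narrow.

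The cellulose and glucose comparison asks the same of an insoluble polymer of glucose. With cellulose, cDNA was lower over 2806001 to 2808500 (668 RPM against 4915 with glucose, log2 -2.88, counting interval -3.09 to -2.68), 2054501 to 2057000 (801 against 4367, log2 -2.45), 106001 to 108000 (209 against 1022, log2 -2.29) and in the window 990501 to 991000 (101 against 875, log2 -3.11). Window 855501 to 856000, which was 3.91-fold higher with cellobiose than with glucose, had 3 placements with cellulose against 208 with glucose (log2 -4.74, interval -7.02 to -3.17). cDNA was higher with cellulose over the adjoining windows 1895001 to 1895500 (424 RPM against 60.8, log2 2.80, interval 2.32 to 3.30) and 1895501 to 1896000 (log2 2.32), in 442001 to 442500 (log2 2.62) and in 114001 to 114500 (log2 2.26). Of 2601 windows, 351 were at least 2-fold higher and 770 at least 2-fold lower.

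Of the 609 repeat windows, 320 were higher and 17 lower, with a median log2 ratio of 1.07. Reads in these windows had a median of 8.07 placements and counted at each, so the 320 windows are not independent. Of the 1992 single-copy windows measured, 31 were higher and 753 lower, with a median of -0.80. This level depends on the scaling, since a read counts in the total at each placement. Outside the locus, cellulose had 276454 placements from 158946 reads, and glucose 834368 from 654204. With singly placed reads only, scaled by TMM, 39 windows were higher and 655 lower. Without TMM, totals of singly placed reads would give higher cellulose to glucose ratios. The count minimum leaves out weak windows. All single-copy windows were therefore also put in 10 classes of rising RACE reads. Their cDNA was taken as singly placed reads over the totals of such reads outside the locus, 617806 for glucose and 140222 for cellulose. On this scale mean cDNA was 2.40 times as high with cellulose as with glucose in the lowest class and 1.22 times in class 7. In classes 9 and 10 it was 0.781 and 0.788 times. These totals give higher ratios than those behind the median of -0.80, so the levels cannot be set against it. The fall across classes does not depend on the totals. The single-copy median was -0.57 over the 399 least abundant windows and -1.22 over the 399 most abundant, so abundance was spread more evenly over windows with cellulose. With that trend removed, an alternative chosen after seeing the data, the split turned, to 659 windows higher and 99 lower, and the 12 named lower windows lay at log2 -4.02 to -1.34 beyond it. The trend was fitted on single-copy windows and subtracted from all windows, so it raised the repeat windows, which were already higher. The split of single-copy windows alone after this step was not counted, so the turn is not shown for them. The other named lower windows started at 720001, 107501, 588001 and 588501, and the other named higher windows at 1362501, 111001, 1005001, 1717001, 1258501, 1861501, 915501 and 29501, the last 8 by 2.66-fold to 3.68-fold. With library totals in place of TMM, the median of all windows moved by 0.21 and 419 windows were higher and 514 lower, and without the low-count filter the split turned, to 1075 higher and 920 lower. The cellulose cDNA library was also the one run on another flow cell, so carbon source and flow cell cannot be told apart in the cDNA ratios.

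**Figure D3:**
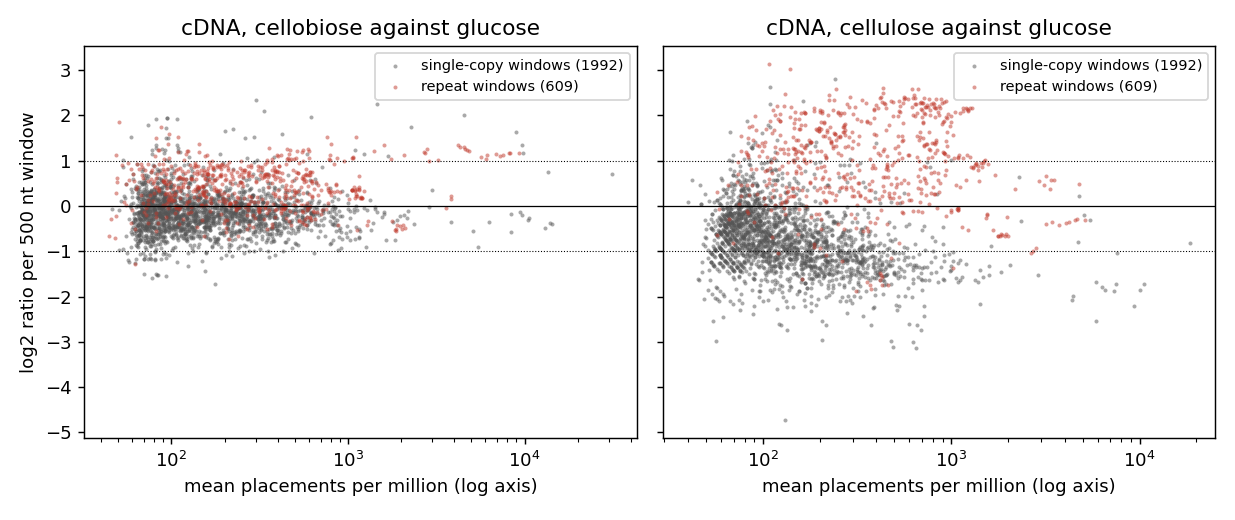
Each point is a 500 nt window, with the log2 ratio of cDNA to glucose for cellobiose on the left and cellulose on the right against the mean RPM on a log axis, grey for the 1992 single-copy windows and red for the 609 repeat windows. In the cellulose panel the repeat windows have a median of 1.07 and the single-copy windows a median of -0.80.

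All 3 RACE libraries shared a flow cell. With cellulose, the site with the highest ratio to glucose was 1895163 on the plus strand, in the window that also had the highest single-copy cDNA ratio, at 262 RPM against 11.6 (log2 3.66). Sites 866441 and 1740665 on the minus strand were higher too (274 against 13.9 and 868 against 148 RPM), as was 1727021 on the plus strand (455 against 78.8). Glucose had only 5 ends at 1895163 and 6 at 866441, and 64 and 34 at 1740665 and 1727021. The site 597874 was higher with cellulose too (207 against 30.1). Among the lower sites were 666126 (12.7 against 788 RPM, log2 -5.13), 426221 (19.1 against 510), 728964 (6.35 against 255), 1759304 (85.8 against 1193) and 416098 (38.1 against 436), all on the plus strand. Of the 12 named windows higher in cDNA, 11 had a site in them or within 100 nt, and of these 11 strongest sites 6 were higher with cellulose and 5 lower, among them 111337 (380 against 1807 RPM) and 915783 (793 against 1232) on the plus strand and 442434 on the minus strand (46.1 against 116). Of the 12 lower in cDNA, 9 had a site, and of these 8 sites 7 were lower and 1 higher, and 2808296 and 107748 on the minus strand were among the lower (47.7 against 188 and 73.9 against 366 RPM). Of 1032 sites, 97 were at least 2-fold higher and 153 at least 2-fold lower. With 5′ ends outside the locus as the total, chosen after seeing the data, the split was 138 higher and 124 lower. The 29 single-copy windows at least 2-fold higher in cDNA had a median RACE log2 ratio of 0.61, above each of 10000 matched random lists (highest 0.59). The 596 at least 2-fold lower had a median of -0.21, below each (lowest -0.12). These called windows adjoin in places too, so the range of the lists may be too narrow here as well.

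The cellulose and cellobiose comparison sets the polymer against the disaccharide. Window 855501 to 856000 had the lowest ratio, with 3 placements with cellulose and 461 with cellobiose (log2 -6.70, counting interval -8.99 to -5.15), and 856001 to 856500 had 11 against 297 (log2 -4.19, interval -5.21 to -3.33). The 5 windows from 2806001 to 2808500 were lower as well (668 against 4655 RPM, log2 -2.80, interval -3.01 to -2.60), as were 990501 to 991000 (6.89-fold), 107501 to 108000 (6.69-fold) and 1653501 to 1654000 (5.73-fold). Windows higher with cellulose included 120501 to 121000 (3.82-fold), 111001 to 111500 (3.65-fold), 29501 to 30000 (2.88-fold) and the stretch 2445001 to 2446500 (576 against 208 RPM, log2 1.47, interval 1.11 to 1.84). In all, 246 windows were at least 2-fold higher and 565 at least 2-fold lower. Of these, single-copy windows gave 29 higher and 534 lower, and repeat windows, which share reads, 217 higher and 31 lower. With library totals in place of TMM the split turned, to 386 higher and 229 lower, and the median of all windows moved by 0.36. Each named window differed by more than this shift. The split turned as well without the low-count filter (690 higher, 645 lower) and with the abundance trend removed (550 higher, 81 lower). That trend was again fitted on single-copy windows only, which raised the repeat windows.

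**Figure D4:**
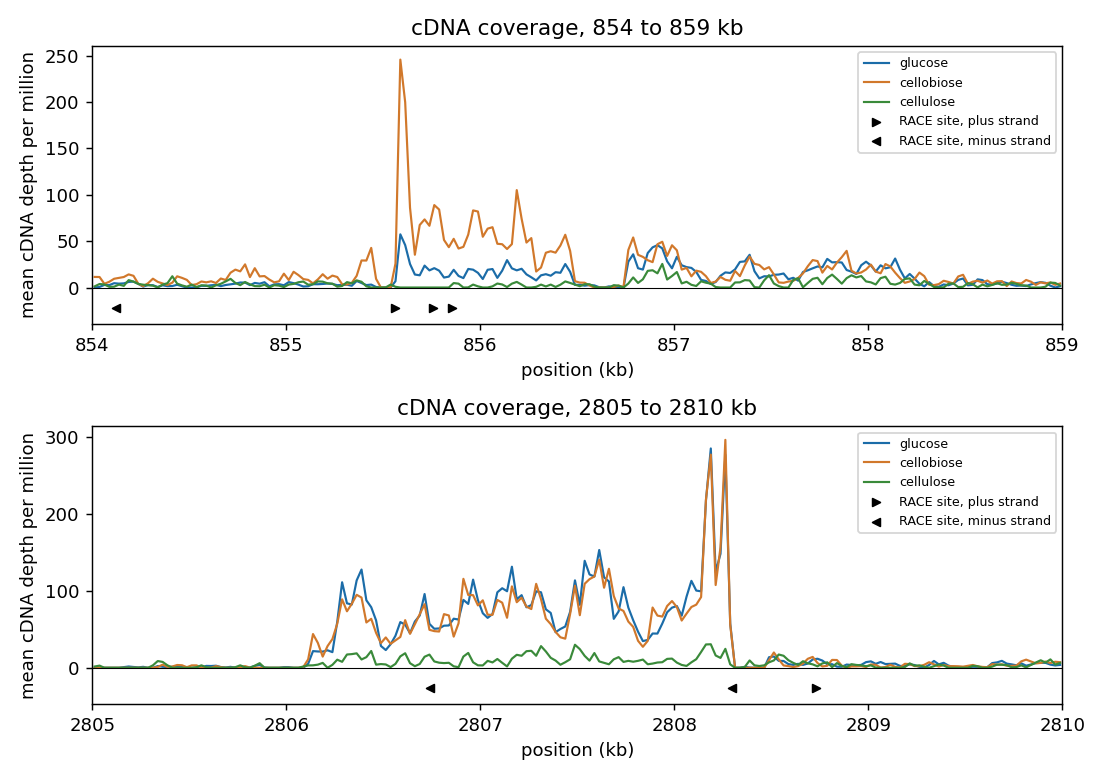
Lines give the mean cDNA depth, scaled as RPM, in bins of 25 nt against position in kb, from 854001 to 859000 and from 2805001 to 2810000, blue for glucose, orange for cellobiose and green for cellulose, and triangles mark RACE sites with at least 50 reads by strand. In the upper panel, cellobiose is highest from 855551 to 856500, where cellulose is near 0, and in the lower panel cellulose lies below both over most of 2806001 to 2808500.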

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

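The 3 tests of the repeat windows were chosen only after the result was seen, while the tests of the low single-copy windows and of the window at 855501 were written before.

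Reads with several placements, which the start-site comparisons left out, held strong signals of their own. Reads shared by plus-strand positions 1949972 and 1950716, 744 nt apart, gave 190276 RACE 5′ ends over the 3 libraries, at 75066 in each 1000000 reads with glucose, 53994 with cellobiose and 36426 with cellulose. Reads shared by 10 positions gave 101162 ends, at 22366, 25459 and 29092 on the same scale. Ends close by followed these ratios only in part: 1949974 and its copy gave 20991, 11820 and 16006, 1949976 and its copy 2658, 1292 and 4537, and near the set of 10, at 1042165 and copies, 1042163 and its copies gave 2173, 1769 and 9975 and 1042146 and its copies 2211, 2817 and 3766. The coverage files held up to 3.36% more depth than the listed placements, the highest being that of the cellulose RACE library.

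Repeat windows were higher in the cellulose cDNA library than with glucose, with a median log2 ratio of 1.07. Listing a read at every placement is argued against as the whole cause, since with each read counted once the share of multiply placed reads was still 2.12 times as high (11.8% against 5.56%). Genomic DNA alone would add no more per copy than to single-copy windows, but the lower quartile of the rise per copy was 1.34 times the largest mean rise among 10 classes of single-copy windows. That quartile covers only the 609 repeat windows past the count minimum, which cellulose reads help a window to pass. The single-copy classes had no such minimum, so the comparison favours a larger rise and does not settle this. Flow cell and carbon source cannot be told apart: in RACE, on 1 flow cell, the cellulose to glucose ratio was 1.64 for reads with at least 5 placements but 1.11 for all multiply placed reads, against 2.47 and 2.12 in cDNA. The carbon source stays open and was not tested.

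Single-copy windows with the fewest glucose and cellobiose reads were higher in the cellulose cDNA library, by 3.75-fold over 1045 windows. The ratios were 2.40, 1.72, 1.25 and 0.755 in the classes above. Choosing by glucose reads itself raises these ratios at the low end. With 10 classes chosen by RACE reads the lowest gave 2.40 and the next 2.12. All of these cDNA ratios are per singly placed read outside the locus, without TMM. The TMM-scaled totals of placements used for the windows would lower them. Genomic DNA in that library as the whole cause is argued against by RACE, whose adapter is ligated to RNA and which was 1.93-fold higher there. That ratio is per singly placed end outside the locus. The locus took more of the cellulose RACE reads, so the ratio would be smaller in RACE RPM. Its bootstrap interval, 1.68 to 2.21, comes from resampling the 1045 windows. With 1 RACE library per carbon source, it leaves out the spread between libraries. The RACE ratio is smaller than the cDNA ratio, so genomic DNA or the flow cell could still add a part. Depth is argued against because, at 100000 reads each, the cellulose library covered 1.32 times as many positions as the glucose library. The carbon source stays open and was not tested.

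Window 855501 to 856000 had 3 cDNA placements with cellulose. A stretch missing from the genome of the whole culture is argued against by 82 singly placed RACE ends with cellulose, 52 on the plus strand and 30 on the minus strand. This holds only if the RACE and cDNA libraries came from the same culture, which was not established here. The plus-strand level was 41.3 RPM, against 334 with glucose and 1081 with cellobiose, while the minus-strand level went the other way, at 23.8 RPM against 0 and 6.05. Loss of part of the window, or loss in part of the culture, could not be excluded. Lower plus-strand transcription with cellulose may be the reason, as a hypothesis that the 82 ends leave open.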

How the results depend on the processing

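The tests with the abundance trend removed, library totals, single-copy windows only, every RACE placement, RACE totals outside the locus, a 50 nt flank and sites with at least 100 reads were chosen only after the data were seen. Of 89 alternatives over 10 results, 68 stayed within 1.5 times the reported count or inside its interval and 21 moved beyond it. The split of higher and lower windows did turn: with library totals for cellobiose against glucose (74 and 89) and cellulose against cellobiose (386 and 229), with single-copy windows only for cellobiose against glucose (45 and 46), and without the low-count filter for cellulose against glucose (1075 and 920) and cellulose against cellobiose (690 and 645). The cause was not tested unless stated. Without the low-count filter, which adds windows, counts at least 2-fold apart were 407 for cellobiose against glucose, 1995 for cellulose against glucose and 1335 for cellulose against cellobiose (169, 1121 and 811 as reported). With singly placed reads only they were 92 and 694 for the first and second of these, and with reads sharing a position and strand counted once 68 for the first. With single-copy windows only, there were 91 for cellobiose against glucose, since this leaves out the repeat windows, of which 12.8% were called against 4.57% of single-copy windows. The edgeR fit on runs called 819, 2241 and 1577 windows, the second split nearly evenly (1125 higher, 1116 lower) and to either side under the alternatives, and a DESeq2 Wald test 264, 909 and 692. With singly placed reads edgeR called 452 for cellobiose against glucose (208 higher and 244 lower, against 487 and 332) and 1035 for cellulose against cellobiose, and with positions counted once 372 for the former. With the replicate block it called 825 for cellobiose against glucose, although the run numbers were not taken as pairs. Leaving out each run in turn gave 151 to 226, 962 to 1160 and 736 to 842 windows at least 2-fold apart, and 414 to 680, 1655 to 2230 and 1110 to 1507 edgeR calls, where the lone run was assumed to vary like the others. The 47 lower windows of cellobiose against glucose became 105 without cellobiose run 2, 80 without cellobiose run 1 and 26 without glucose run 2. The cellobiose edgeR count was 423 without glucose run 2 and 414 without cellobiose run 2. The 4840 start sites became 2716 at a minimum of 10 reads, 7435 at 3 reads and 2432 when all 3 libraries had to pass, by construction. A RACE pseudocount of 50 RPM left 47 and 139 sites in place of 154 and 250, since it shrinks ratios of weak sites. The splits were then 28 higher and 19 lower for cellobiose, and 33 and 106 for cellulose. Step sites were 60.59% among sites with at least 100 reads, against 33.26%. With the abundance trend removed, the split turned for both cellulose comparisons: windows split 182 higher and 24 lower for cellobiose against glucose, 659 and 99 for cellulose against glucose and 550 and 81 for cellulose against cellobiose. These splits take in repeat windows, which were raised by a trend fitted on single-copy windows only. With RACE totals outside the locus, sites split 159 higher and 30 lower for cellobiose and 138 and 124 for cellulose, which turned from 97 and 153. Alternatives for gene lists, leaderless share, site location, promoter A+T share, Shine-Dalgarno motif and operon continuity were not run. Depth outside the locus, 155237 to 453094 cDNA reads per library, limits weak windows.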

Other observations

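The test of the locus lengths and the count of site pairs were chosen only after the data were seen.

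Strong start sites, with at least 100 reads, lay back to back more often than shifted sites did. Of the 545 plus-strand and 574 minus-strand sites, 43 of the plus-strand sites had a minus-strand site within 200 nt upstream, pointing away, against a mean of 18.4 (6 to 38) over 1000 circular shifts of the minus-strand sites. Plus-strand sites with a minus-strand site facing them within 200 nt downstream numbered 2, against a mean of 18.7 (5 to 41).

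A hypothesis for the locus from 871501 to 876500 is that it holds the 16S and 23S ribosomal RNA genes. Its covered blocks of 1451 and 3041 nt were compared with genes of 1499 and 3051 nt in a gene table of another strain, and the larger difference was 3.20%. The lengths are consistent with this, but sequence was not compared, and the gene table is that of the SULM assembly.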
